A study of Mus musculus with 4 samples.

How the data were processed

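Gene expression was measured by SMART-seq2, a full-length cDNA method for small cell numbers, in γδ T cells sorted by flow cytometry from the epididymal fat of male C57Bl/6 mice that carry a GFP reporter of PLZF. PLZF is the transcription factor encoded by Zbtb16. There were 2 libraries of PLZF+ cells and 2 of PLZF- cells, each from a pool of 10 mice aged 16 to 22 weeks, per the labels. The labels do not say whether a PLZF+ and a PLZF- library came from the same mice, and the antibodies and gates of the sort are not given in the sources used here. The table columns name the subset and a code (A6 and B6 for PLZF- cells, A7 and B7 for PLZF+ cells) and carry no replicate number. No label says what the codes are, and they are read here as plate wells. Libraries are therefore named by subset and well.

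Per the submitters' processing notes, reads were aligned to mm10 and processed with HISAT 0.1.6, SAMtools 1.2, Cufflinks 1.2 and Cuffdiff. The gene annotation and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The authors deposited a Cuffnorm table of normalized counts, which holds estimated counts divided by a factor per library, a signal and not raw counts. They also deposited a Cuffnorm table of FPKM, and a Cuffdiff table with a log2 fold change, a p-value and a q-value for each of 46799 loci. The log2 fold change column of the authors' deposited table holds unreadable entries at 1321 loci. The direction of its calls was therefore read from the group means of the deposited FPKM table.

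Each locus was named from its deposited symbols through GENCODE M21 on GRCm38 (the assembly of mm10) and RefSeq synonyms. A name was refused where the annotated gene did not overlap the locus, which happened 533 times. Overlapping loci of one name were summed, which left 46099 genes, 542 of them from more than 1 locus. A locus that holds several genes is given with all their names, joined by a slash, and its value is not assigned to one of them. Coordinates are on mm10, 1-based.

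The low values of each library are multiples of a step, the value of 1 read. The step was 1.69 (A6), 0.619 (A7), 1.22 (B6) and 0.558 (B7) normalized counts, and 92.4% to 94.2% of values lay within 0.05 of a whole number of reads. The rRNA precursor Rn45s was listed at 0 in PLZF+ library B7 and took 26.8%, 28.1% and 33.2% of the total in A6, A7 and B6. That 0 was treated as a failed estimate, and Rn45s was left out of totals and tests. Without it the estimated reads were 744570 (A6), 981887 (B6), 1837508 (A7) and 2035062 (B7). Where both libraries of a subset had 0 reads, the fold is a lower bound against 3 reads per library, averaged over the subset. Where a subset had 1 to 3 reads, the ratio is given with its exact 95% interval. Such bounds and intervals cover counting error only, because PCR copies are not independent molecules.

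Genes with a mean normalized count of at least 10 were tested (9254 genes). The test was limma 3.58.1 in R 4.3.3, with a trend and robust empirical Bayes moderation, two-sided, on log2(normalized count + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. Gene lists with at least 5 tested members (20 of 30) were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera compares a list with the other genes, while fry tests its members against no change. With an estimated correlation, camera takes its degrees of freedom from the libraries and not from the genes, so few libraries alone raise its p-values. The p-values of both are adjusted over those lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Tested on data simulated for the comparison of PLZF+ with PLZF- cells over 9254 genes, the fit called 38% of genes changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. It called 6 of 9054 unchanged genes. The simulation gave every gene of both subsets the same spread, estimated from these libraries (dispersion 0.035). Its rates therefore do not cover genes or a subset that vary more. Each library is a pool of mice, so the p-values measure the spread between pools and not between single mice.

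The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes 14 genes of the γδ T cell subsets, whether or not they pass, then the 10 largest changes in each direction among genes past the threshold whose subsets do not overlap, and up to 4 members of each list with the smallest p. Predicted and clone-named genes and gene segments were left out of the largest changes. Any other gene named was chosen after its values were seen. Alternatives fixed with them were pseudocounts of 0.25 and 4, no filter, a minimum mean of 50, median-ratio and equal-total scaling, the FPKM table, each library left out, moderation without trend or robust fitting, an estimated inter-gene correlation, fry, and the authors' Cuffdiff calls. A further 5 were added after the data were seen: voom on estimated reads, reads thinned to the shallowest library, loci that name 1 annotated gene, loci not summed, and the well letter as a term. Some genes named in advance or by the rule on ranks are not reported here.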

Results

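Transcripts of γδ T cells from mouse epididymal fat were compared between cells that did and did not express a PLZF reporter. γδ T cells are lymphocytes with a γδ antigen receptor, and the title of the study concerns those that make IL-17A. There were 2 PLZF+ libraries (wells A7 and B7) and 2 PLZF- libraries (A6 and B6), each from a pool of 10 mice. The estimated depth without rRNA precursor was 1837508 and 2035062 reads in the PLZF+ libraries and 744570 and 981887 in the PLZF- libraries. Across tested genes, log2 values correlated at r = 0.89 between the PLZF+ libraries, 0.80 between the PLZF- libraries and 0.60 to 0.71 between subsets. Genes are not independent replicates, so these values only describe the libraries.

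Zbtb16, which encodes PLZF (chromosome 9, 48635689 to 48861092, mm10), had 2910 ± 15.8 normalized counts in PLZF+ and 505 ± 275 in PLZF- libraries (SD, n = 2 each). The log2 fold change was 2.64 ± 0.31 (SE, adjusted p = 0.00051, limma). The cells were sorted on a reporter of this gene, so it checks the labels and is no finding. Without the trend and the robust fit the adjusted p was 0.10.

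Of 9254 tested genes, 232 were higher and 462 lower in PLZF+ cells. Of the 694, 391 differed at least 4-fold. Both libraries of one subset lay beyond both of the other for all 694, and for 51.3% of tested genes against 33.3% by chance. The call counts depended on single libraries: 22 genes were higher without PLZF+ library B7, 29 without A7, and 101 without PLZF- library A6, while 104 were lower without A6, 224 without B6 and 211 without B7. Without the trend and the robust fit 27 were higher and 180 lower. In the authors' deposited table, 168 loci were higher and 361 lower. Of the genes with such a locus, 127 of 167 higher and 235 of 360 lower were also called here, and 0 were called in the other direction.

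**Figure D1:**
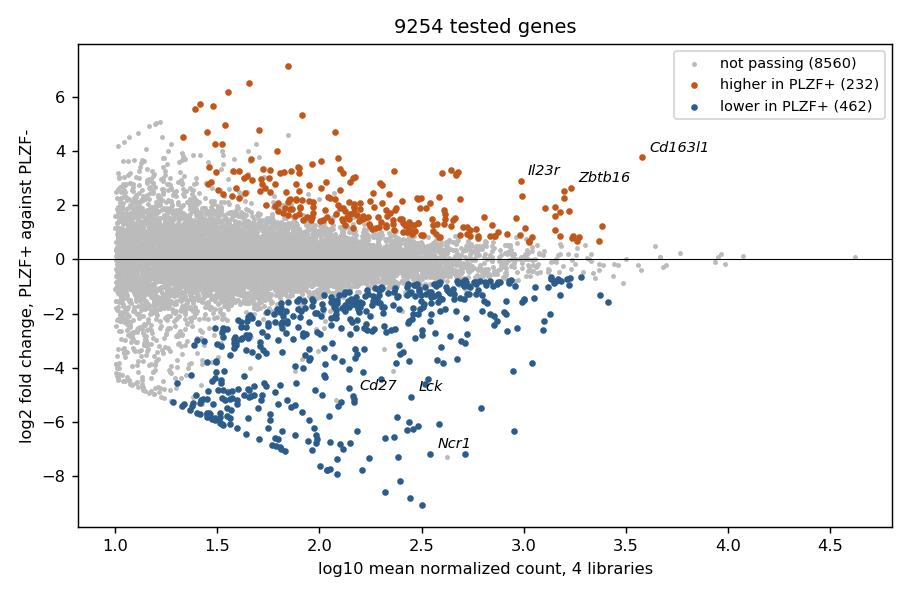
Each point is 1 of 9254 tested genes, with log10 of its mean normalized count over 4 libraries on the x axis and its log2 fold change, PLZF+ against PLZF-, on the y axis. Orange points are the 232 genes higher in PLZF+ cells, blue points the 462 lower, and grey points did not pass.

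Genes of the IL-17-producing γδ T cell programme were higher in PLZF+ cells. Of 24 tested members, 19 rose, 1 fell and 4 did not pass (20 and 1 adjusted over the list alone), with a median log2 fold change of 2.20. The member that fell was 5830411N06Rik (-1.82). Cd163l1, a scavenger receptor known as SCART1, had 7038 ± 563 normalized counts against 534 ± 193 (log2 fold change 3.76 ± 0.22, adjusted p = 5.6e-06). The receptor genes Il23r and Il1r1, which carry the IL-23 and IL-1 signals that drive IL-17, rose by 2.89 ± 0.22 and 3.16 ± 0.32, and Blk, a Src-family kinase, by 3.11 ± 0.30. Camera gave an adjusted p of 7.3e-20 for the list, and the adjusted p = 0.24 with an estimated correlation.

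Of the IL-17 cytokine genes, Il17f was low in both subsets (means of 18.6 normalized counts in PLZF+ and 16.9 in PLZF- libraries). Il17a had 206 and 65.3 normalized counts in PLZF+ libraries A7 and B7 and 10.1 and 25.6 in PLZF- libraries A6 and B6 (log2 fold change 2.77 ± 0.64, adjusted p = 0.020). The call was lost when any library was left out, with adjusted p from 0.061 to 0.45, and also without a filter (0.11) and by voom, a setting chosen after seeing the data (0.22). Il17f (log2 fold change -0.28, adjusted p = 0.90) and Ccr6, a chemokine receptor (-0.14, adjusted p = 0.93), did not pass. Maf, a transcription factor of these cells, rose by 1.09 ± 0.22 (adjusted p = 0.010), and lost its call without A6, A7 or B7, by FPKM (0.070) and without a filter (0.053). Pdcd1, which encodes the inhibitory receptor PD-1, rose by 1.75 ± 0.18 (adjusted p = 7.3e-05). Tnf had a log2 fold change of 1.25 (adjusted p = 0.17). Without the trend and the robust fit 35 of the 99 named genes other than Zbtb16 lost their calls, among them Il1r1, Pdcd1, Il17a and Maf (adjusted p 0.056, 0.11, 0.18 and 0.26). Some of the 99, such as Il17f and Ccr6, had no call to lose.

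**Figure D2:**
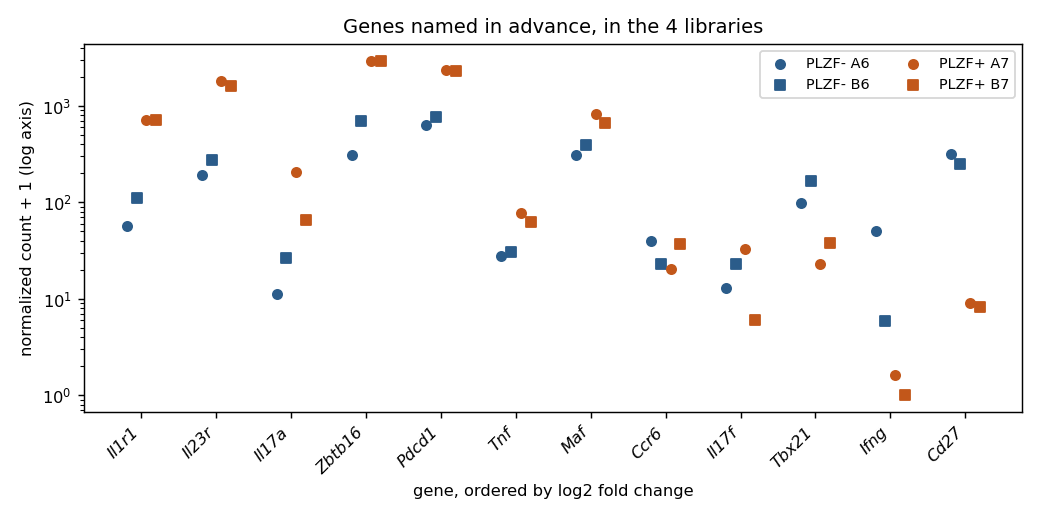
Normalized count + 1 on a log axis for tested genes among those named in advance, in each of 4 libraries. Blue is PLZF- and orange PLZF+, circles are A wells and squares B wells. Il1r1 and Il23r lie higher and Cd27 lower in both PLZF+ libraries, while Il17f and Ccr6 overlap.

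Type 1 and cytotoxic genes were lower in PLZF+ cells. Of 27 tested members, 24 fell and 0 rose (24 adjusted over the list alone), with a median log2 fold change of -5.15 (camera adjusted p = 5.7e-29, adjusted p = 0.13 with an estimated correlation). Ncr1, an activating receptor of natural killer cells, had 694 and 693 normalized counts in PLZF- libraries and 3.91 and 3.72 in PLZF+ libraries. Nkg7, a granule protein gene, and Il12rb2, an IL-12 receptor chain, fell as well (log2 fold changes -5.82 and -7.28). Cd27, a co-stimulatory receptor of interferon-producing γδ T cells, fell by 5.03 ± 0.47 (adjusted p = 4.8e-05). Tbx21, which encodes T-bet, fell by 2.13 ± 0.48 (adjusted p = 0.016) and lost its call when any library was left out, as it did without the trend and the robust fit (0.14) and without a filter (0.075). Ifng had 48.9 and 4.88 normalized counts in PLZF- libraries and 1 read in PLZF+ libraries, a ratio of 79.6 (95% counting interval 13.3 to 3237), and did not pass (adjusted p = 0.28). Eomes lay under the filter, with 20 reads in PLZF- and 0 in PLZF+ libraries.

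Markers of other innate lymphocytes moved with that list. Of 12 tested innate lymphoid and natural killer markers, 11 fell and 0 rose (12 adjusted over the list alone, median -6.11, camera adjusted p = 7.3e-20, adjusted p = 0.24 with an estimated correlation). Il5, a cytokine of group 2 innate lymphoid cells, had 707 and 494 normalized counts in PLZF- and 17.3 and 2.79 in PLZF+ libraries. Gata3 fell by 2.83 ± 0.24. Il1rl1, which encodes the IL-33 receptor, fell by 7.19 (adjusted p = 0.016, and 0.062 without PLZF- library A6). The locus of Klrb1b and Klrb1c fell by 4.40 ± 0.41.

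Dendritic cell and MHC class II genes were also lower in PLZF+ cells. Of 11 members, 4 fell and 0 rose (8 adjusted over the list alone, median -3.61, camera adjusted p = 5.9e-07, adjusted p = 0.24 with an estimated correlation). Siglech had 145 and 90.2 normalized counts in PLZF- and 0 in both PLZF+ libraries, at least 66.6-fold lower. Itgax and Cd74 fell (log2 fold changes -5.20 ± 1.02 and -3.61 ± 0.74), as did H2-Aa (162 and 146 against 20.4 and 3.35 normalized counts). Without A6 the adjusted p of Siglech, H2-Aa, Itgax and Cd74 was 0.14, 0.13, 0.23 and 0.22, and without B6 0.063, 0.080, 0.086 and 0.087. Itgax and Cd74 also lost their calls without B7 (log2 fold changes -3.47 and -2.29, adjusted p 0.055 and 0.080). Jchain, the immunoglobulin joining chain, was at least 238-fold lower (0 reads in PLZF+ libraries). Of 6 mast cell and granulocyte markers 1 fell, Kit (4 adjusted over the list alone, camera adjusted p = 0.00020, adjusted p = 0.32 with an estimated correlation). The camera adjusted p was 0.058 without PLZF- library A6.

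Naive and lymphoid-homing genes were lower in PLZF+ cells, with 8 of 14 falling and 0 rising (11 adjusted over the list alone, median -2.54, camera adjusted p = 1.1e-11, adjusted p = 0.17 with an estimated correlation). Itga4 and Satb1, a chromatin organiser, fell (log2 fold changes -3.09 ± 0.27 and -2.28 ± 0.28). The locus shared by Ly6a, Ly6c1 and Ly6c2 fell by 3.70 ± 0.30. Of 19 tissue residency and activation genes, 10 fell and 1 rose (11 and 3 adjusted over the list alone, median -0.75, camera adjusted p = 8.0e-05, adjusted p = 0.32 with an estimated correlation). Nr4a1 and Itgav fell (log2 fold changes -2.27 and -1.80), while Icos, a co-stimulatory receptor, rose by 1.53 ± 0.25 and lost its call without A7 or B7 (adjusted p = 0.10 and 0.080). Of 18 inhibitory receptors and co-stimulators, 9 fell and 2 rose, also 9 and 2 adjusted over the list alone (median -1.80, camera adjusted p = 0.00064, 0.12 at a minimum mean of 50, adjusted p = 0.24 with an estimated correlation). Tnfrsf18 and Tigit fell (log2 fold changes -2.78 and -3.72), and Cd244a had 1 read in PLZF+ libraries, a ratio of 581 (95% counting interval 103 to 23048, adjusted p = 0.11 without A6).

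Genes of T cell receptor signalling moved both ways. Of 27, 7 rose and 9 fell (7 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.16). With the well letter as a term, a setting chosen after seeing the data, it passed as lower (0.033). Fry, which tests members against no change and not against other genes, gave an adjusted p of 0.0095. Lck, the Src-family kinase of the receptor, had 538 and 554 normalized counts in PLZF- and 12.4 and 19.0 in PLZF+ libraries (log2 fold change -5.06 ± 0.38, adjusted p = 1.4e-05). Ptprc, Txk and Ptpn22 fell (log2 fold changes -1.59, -2.26 and -1.57). The γδ receptor locus that holds Tcrg-C3, Tcrg-V5 and Tcrg-V6 rose by 2.52 ± 0.18 (2511 and 2835 against 440 and 488 normalized counts), and the other of the 2 tested loci in the fixed list of segments did not pass. Innate cytokine receptors rose in 7 and fell in 7 of 25 cases (8 and 8 adjusted over the list alone, camera adjusted p = 0.71). Il18rap fell by 2.26. Of 19 secreted cytokines, 3 rose and 4 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.12, but 0.0039 without a filter, 0.0068 without A7 and 0.011 with the well letter, each as lower), among them Csf2 and Areg, which fell (log2 fold changes -6.57 and -3.63), and Xcl1 (1 read in PLZF+ libraries, a ratio of 215, 95% counting interval 37.5 to 8571). Without B6 the adjusted p of Areg was 0.061, and that of Xcl1 was 0.098 without B6 and 0.21 without A6.

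Glycolysis, proliferation, clock, ribosomal protein and oxidative phosphorylation lists were higher in PLZF+ cells by camera, by small amounts. Glycolysis genes had a median log2 fold change of 0.33, with 3 of 19 rising (Hk2 by 1.83 ± 0.37, Pkm by 0.85 ± 0.20, Pfkp by 0.89 ± 0.21, 5 adjusted over the list alone, camera adjusted p = 0.0051, adjusted p = 0.24 with an estimated correlation). Each of these 3 lost its call without A6, A7 or B7 (adjusted p 0.072 to 0.33), and Pfkp also without B6 (0.071). Proliferation genes had 2 of 22 rising, Cdk1 and Stmn1 (2 adjusted over the list alone, median 0.77, camera adjusted p = 0.00024, adjusted p = 0.24 with an estimated correlation). Cdk1 and Stmn1 lost their calls without A6, A7 or B7 (adjusted p 0.066 to 0.73), and Stmn1 also without B6 (0.056). Of 14 circadian clock genes, 2 rose, among them Nr1d1 by 3.17 ± 0.56 (4 higher and 1 lower adjusted over the list alone, median 0.48, camera adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation). Nr1d1 lost its call without A7 or B7 (adjusted p = 0.12 and 0.14), and the clock list had a camera adjusted p of 0.077 without B6, 0.13 without a filter and 0.075 on loci of 1 gene, a setting chosen after seeing the data. No member of the ribosomal protein (79 genes, median 0.39) or oxidative phosphorylation lists (30 genes, median 0.45) passed by limma, and 0 passed adjusted over the list alone. Their camera adjusted p was 7.2e-08 and 0.00080, and the adjusted p = 0.33 and 0.24 with an estimated correlation.

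Some immediate early genes were lower in PLZF+ cells. Of 23 tested members of the list of immediate early and heat shock genes 5 fell, none of them one of the 6 heat shock genes (12 adjusted over the list alone, median -1.10, camera adjusted p = 7.2e-08, adjusted p = 0.24 with an estimated correlation). Nfkbiz, Nfkbia, Btg2 and Atf3 fell (log2 fold changes -3.23, -1.60, -0.87 and -1.70). Nfkbia, Btg2 and Atf3 lost their calls without A6 or B7 (adjusted p 0.076 to 0.29), Nfkbia and Atf3 without B6 (0.061 and 0.087), and Btg2 without A7 (0.11). The heat shock genes of this list differed between libraries of one subset: Hspa1a had 278 and 14.6 normalized counts in PLZF- libraries A6 and B6 and 127 and 0 in PLZF+ libraries A7 and B7. Of 15 interferon-stimulated genes 0 passed (0 adjusted over the list alone, median -0.71, camera adjusted p = 0.024, adjusted p = 0.24 with an estimated correlation). The camera adjusted p was 0.37 at a minimum mean of 50, 0.058 without A7, 0.077 without B6 and 0.096 with the well letter. Fatty acid and cholesterol genes (1 of 26 fell, Abca1, also 1 adjusted over the list alone, with adjusted p = 0.22 without A6 and 0.10 without B6, camera adjusted p = 0.25) and histone genes (0 of 6, also 0 adjusted over the list alone, camera adjusted p = 0.98) did not pass.

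Few listed markers of most other cell types in fat reached the filter. Tested members numbered 1 of 17 B cell, 4 of 17 adipocyte, 4 of 13 αβ T cell, 2 of 14 endothelial, 2 of 22 macrophage, 1 of 18 epididymal epithelium, 1 of 19 stromal and 0 of 10 erythroid markers. These are counts of listed symbols, of which 16 B cell, 8 αβ T cell and 7 erythroid ones were measured, so the unmeasured ones were not shown to be low. Some tested markers were well above the floor, such as Ikzf2 of the αβ T cell list (means of 320 in PLZF- and 301 in PLZF+ libraries). None of the tested members passed by limma, and neither did the 3 mitochondrial loci. The smallest adjusted p was 0.13, for Cd79b. Adjusted over its list alone, Cd79b was higher (0.016) and the macrophage marker Ctss lower (0.043) in PLZF+ cells, and without a filter the macrophage list was lower by camera (adjusted p = 0.0015).

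**Figure D3:**
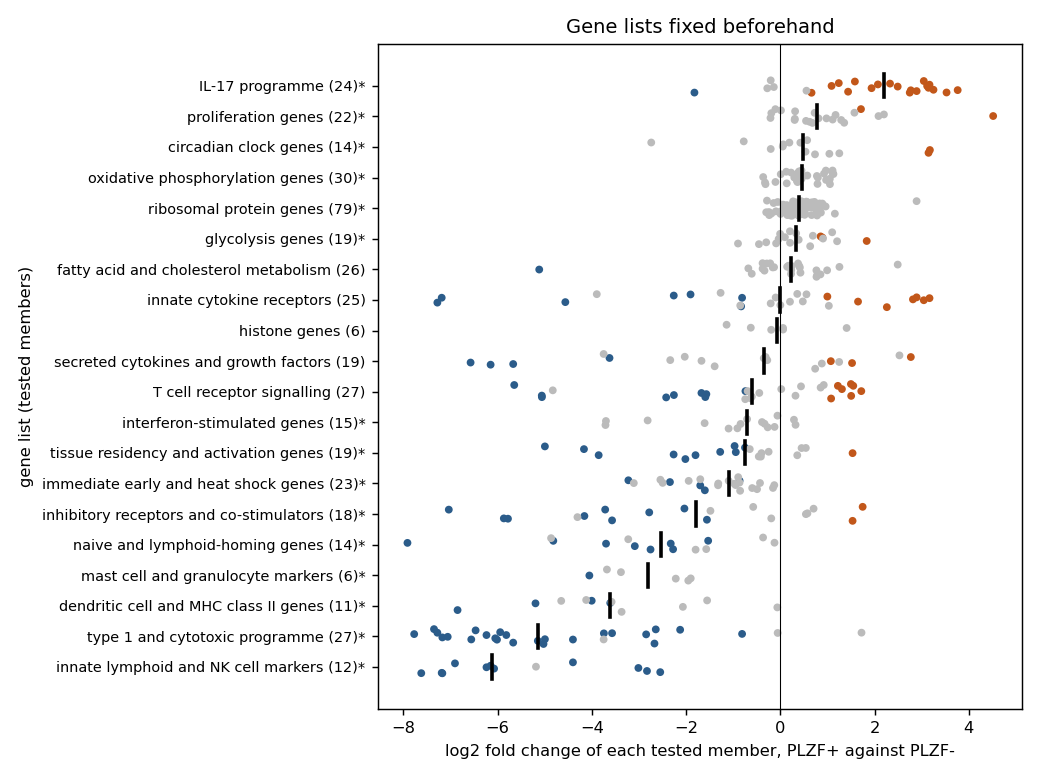
Log2 fold change, PLZF+ against PLZF-, of each tested member of 20 gene lists, with the number tested in brackets and the median as a black bar. Orange and blue points passed over all genes, and an asterisk marks a camera adjusted p under the threshold, for example the IL-17 programme (median 2.20) and the type 1 and cytotoxic programme (median -5.15).

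The largest rises with non-overlapping subsets were in Tdrd9, Cdh10, Fstl4 and Rapsn, which had 0 reads in PLZF- libraries and were at least 32.0-fold, 20.7-fold, 16.3-fold and 11.9-fold higher in PLZF+ libraries. Thbd (log2 fold change 5.32), Ppp1r14c (4.76) and Avpi1 (4.70) followed, with Mtcl1, Olfml3 and Cdk1, each with 2 or 3 reads in PLZF- libraries. Without A7 or B7 each of these calls was lost (adjusted p 0.11 to 0.75), except that of Thbd without A7, and those of Ppp1r14c (log2 fold change then 3.05) and Cdk1 were also lost without A6. The ratios of Mtcl1, Olfml3 and Cdk1 were 31.2 (95% counting interval 10.6 to 153), 25.6 (8.62 to 125) and 29.2 (7.95 to 244). Among the largest falls were those of Jchain, Fasl, Samd3, Klrd1, Il12rb2, Il1rl1, Ncr1, Klre1 and the locus of Klra10, Klra3, Klra8 and Klra9. Samd3, the Klra locus and Klre1 were at least 123-fold, 114-fold and 76.8-fold lower. Without A6 the adjusted p of Samd3, the Klra locus and Klre1 was 0.070, 0.087 and 0.12, and that of Klre1 was 0.055 without B6. Reads of the Klra genes are shared between near-identical copies, so their locus is uncertain. Fasl and Klrd1 had 2 reads each in PLZF+ libraries, with ratios of 533 (95% counting interval 147 to 4414) and 416 (114 to 3448).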

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

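The settings of voom, thinning, loci of 1 gene, loci not summed and the well letter were chosen after seeing the data. No paired analysis was possible because the replicate numbers of the labels do not appear in the columns. The fit with the well letter as a term blocks on wells A and B instead, and no label says that this pairs the libraries. Depth limits the low genes most, since 1 read stands for more normalized counts in PLZF- than in PLZF+ libraries.

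The main counts were 232 genes higher and 462 lower. They stayed within 1.5 times of this under both pseudocounts, a minimum mean of 50, both rescalings, the FPKM table, voom, loci of 1 gene, loci not summed and the authors' Cuffdiff calls. By FPKM 131 of the 232 and 292 of the 462 were kept. The sign by FPKM was the other one for 1 gene called in the main fit, whether or not it passed by FPKM. Without a filter they were 109 and 274, with 15949 genes tested. Without trend and robust fitting they were 27 and 180, and the cause was not tested. Leaving out 1 library gave 22 (without PLZF+ B7) to 246 (without PLZF- B6) higher and 104 (without PLZF- A6) to 274 (without PLZF+ A7) lower, with fewer samples in each fit. The higher share of calls was 33.4% in the main fit and 40.3% under equal totals, and ran from 9.4% (without B7), 9.6% (without A7) and 13.0% (without trend and robust fitting) to 49.3% (without A6) and 52.3% (without B6). With the well letter as a term, 428 were higher and 692 lower, at 1 residual degree of freedom. Over 20 thinned draws 186 to 238 were higher and 388 to 463 lower.

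Zbtb16 stayed higher in each setting run (log2 fold change 2.06 to 3.22). It passed in each but the fit without trend and robust moderation (2.64, adjusted p = 0.10). Of 6 lists higher and 9 lower by camera, 0 and 0 passed with an estimated correlation. That estimate lay under the preset 0.01 for some, such as the type 1 and cytotoxic list (0.0029) and the naive and lymphoid-homing list (-0.0023). A correlation above the preset thus does not account for the loss in these. For others, such as the IL-17 programme (0.39), the estimate lay above the preset. In this setting camera takes its degrees of freedom from the libraries of the fit, 2 per subset, and not from the number of genes. A list that did not pass there is therefore not shown to have correlated genes. By fry 4 lists were higher and 7 lower, of which 10 were among the 15 that passed by camera and the other was T cell receptor signalling. The immediate early and heat shock, mast cell and granulocyte, oxidative phosphorylation, ribosomal protein and tissue residency lists did not pass by fry. The 99 other named genes include some that did not pass in the main fit. Such genes had no call to lose and kept their side by staying above the threshold. Of the 99, 35 kept both their sign and their side of the threshold in every setting that tested them, and 35 lost their calls without trend and robust fitting. The sign turned for 5, none past the threshold: Acaca (-0.0095 by FPKM) and, over the fits without 1 library, Il17f (-1.51 to 0.95), Ccr6 (-0.58 to 0.30), Hist1h1c (-0.52 to 0.13) and the Hist3h2a/Trim17 locus (-1.47 to 0.21). The cause was not tested.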

Other observations

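The tests of B cells, of depth and of Y-linked genes were chosen only after the result was seen, as were the bootstrap intervals of the 3 marker lists and the regard to their level in PLZF+ cells. The genes named in this part were also chosen after their values were seen, apart from those of the fixed lists.

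Genes of the receptor complex and of its signalling moved both ways. Cd3d, Cd3g, Cd247, Lat and Zap70 were higher in PLZF+ cells (log2 fold changes 1.08, 1.55, 1.5, 1.72 and 1.31), as were the Tcrd/Trdd2 locus (1.79) and a Tcrg entry (1.09). That Tcrg entry has the same coordinates as the locus of Tcrg-C3, Tcrg-V5 and Tcrg-V6 above, so these are not separate loci. Cd28 and Cd2 were lower (-4.16 and -2.42), as was Lck (-5.06), while its relative Blk was higher (3.11). A Tcrb locus was lower (-2.0), with 2565 and 1741 normalized counts in PLZF- and 616 and 449 in PLZF+ libraries, while a second entry at the same coordinates, Tcrb/Trbj1-7, did not pass (-0.20, adjusted p = 0.78). Reads at these receptor loci are shared between many segments.

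Some genes known from group 2 innate lymphoid cells were higher in PLZF- libraries: Il5, Il1rl1, Gata3, Calca, Arg1 and Ccr8 (log2 fold changes -6.15, -7.19, -2.83, -3.01, -2.55 and -6.76). Lower depth of the PLZF- libraries is argued against: these libraries were the shallower ones, yet 12 of the 12 tested members of the innate lymphoid and natural killer list had more estimated reads there before any scaling. Innate lymphoid cells in the PLZF- sort may contribute: the 14 tested of 28 genes of such cells, listed before their values were seen, had a median of -0.82. Of the 14, 3 were lower and 1 higher, and the median was at percentile 0.18 of 10000 matched random lists. That median missed the -2 set in advance for such cells and met the bound of above -1 set against them, but its bootstrap 95% interval (-2.78 to 0.26), added after this was seen, spans both bounds. So this stays open, as does expression by PLZF- γδ T cells themselves.

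Immunoglobulin loci and Siglech were higher in PLZF- libraries, the heavy chain locus Igh with 2875 and 687 against 13.6 and 20.1 normalized counts. B cells are argued against as the source of Igh: 9 of 16 measured markers, Cd79a and Ms4a1 among them, were listed at 0 in both PLZF- libraries, though Blnk (10.1 and 8.54), Fcrla (5.06 and 3.66) and, in A6, Ly6d (21.9) and Btk (6.75) were seen in PLZF- libraries alone, and Pou2af1 had 15.2 and 3.66 against 1.24 and 3.35. Plasma cells stay open: the 10 tested of 18 listed genes had a median log2 fold change of 0.42 (bootstrap 95% interval -0.38 to 1.41), above the -1 set in advance against such cells. Of the 10, 2 were higher and 1 lower in PLZF+ cells. But the median level of these genes, 124 normalized counts in PLZF+ libraries, would hide a small share, and Jchain was at least 238-fold lower in PLZF+ cells. Irf4, which did not pass, had 8.44 and 6.10 normalized counts in PLZF- and 88.6 and 14.0 in PLZF+ libraries, so the point about level does not cover it. Plasmacytoid dendritic cells may contribute: the 13 tested of 26 genes listed before their values were seen had a median of -3.49 (interval -3.87 to -0.54). It lay below all 10000 random lists, though of the 13 only Irf8 passed, and Grn, Ctso and Runx2 were at like levels in both subsets. Genes of the list that were not tested do not enter the median. Spib and Tlr7 had 0 in both PLZF+ libraries, and Ctsl, Lair1, Mpeg1, Nucb2, Plac8 and Pld4 had means under the filter of 10 there. All of these passed the filter through their values in PLZF- libraries. The median level of the 13 was 7.96 normalized counts in PLZF+ and 40.1 in PLZF- libraries. The median of -3.49 thus rests in part on this selection. Of 2 further markers left off that list because their values had been seen, Tcf4 was lower in PLZF+ cells (-5.10) and Bst2, abundant in such cells, did not pass (-0.34), and expression by PLZF- γδ T cells was not tested.

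The mice are labelled male, yet Xist, the RNA of the inactive X of female cells (chromosome X), had 500 and 762 normalized counts (296 and 1230 reads) in A6 and A7 and 0 reads in B6 and B7, and the 6 tested heat shock genes were higher in the A well of both subsets (median log2 differences 2.93 and 1.89). The A wells had fewer reads in total (ratios A to B 0.76 and 0.90), which a first test of depth had asked for, yet 6 of the 6 heat shock genes had more reads there in both subsets before any scaling, which argues against sequencing depth. RNA of female mice in the A wells may be a source of Xist, but Y-linked genes were not lower in both A wells (median ratio A to B 1.07 for PLZF- and 0.70 for PLZF+, over 4 genes), which leaves it open. No label says that the letters A and B stand for plate rows. Material or handling shared by a plate row was set to need r above 0.1 between the A minus B differences of the subsets over all other genes. The value was 0.054, which counts against such sharing. That bound ignored counting noise, and with minimum means of 50, 200 and 1000, chosen after that result, r was 0.10, 0.18 and 0.38. Sharing by a row thus stays open.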
